A study of Arabidopsis thaliana with 5 samples.

How the data were processed

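Genomic DNA of 10 plants was sequenced as 5 barcoded libraries of about 10 kb inserts on the PacBio Sequel, 4 from a plant each and 1 from a pool of 6 plants. Per the series' design text, structural variants were called with NGMLR alignment and Sniffles. The versions and settings are not given in the sources used here. The genome build is TAIR10, per the submitters' processing notes. For each library the authors deposited an unfiltered and a filtered list of calls, each with a pair of positions, a type, a predicted length and the count of split reads that support the call. This count is the authors' own, as deposited, and was not normalized. No call in the filtered lists had fewer than 5 reads. The rule of the authors' filter is not given in the sources used here. Set side by side, the filtered lists held none of the calls that touch the chloroplast or the mitochondrion, and none of the joins between the ribosomal RNA loci of chromosomes 2 and 3. The 5 unfiltered lists held 634 calls and the filtered lists 291. In 41 rows of the unfiltered lists the first position columns held placeholders, and the caller's best positions were used. Positions are printed as the lists give them, and whether they count from 0 or 1 is not stated. The length column of a translocation is not a length and was not used as one. Lengths of other calls are predicted lengths, which can differ from the distance between the printed positions.

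Single-plant libraries were grouped by exposure from their labels, 2 Antarctic and 2 simulated. They are separate plants, picked as mutants, so the calls are no estimate of a rate over all seeds. The replicate numbers of the groups do not overlap, and no pairing was used. Depth or coverage per library was not part of the lists, so no call rate per sequenced base was computed, and a call that is missing from a library can mean too few reads. Calls matched when type and chromosomes were the same and both breakpoints lay within 500 bp. A call was private when no unfiltered list of another library held a partner. Repeat calls of a library that matched each other were merged into distinct calls for placements, gene lists and gene naming, and were kept for counts per library.

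Gene names came from a RefSeq gene table of assembly TAIR10.1, with 27562 protein-coding genes. Its assembly name differs from TAIR10. Gene overlaps rest on both having the same nuclear positions, and none of the table's coordinates is printed. As a partial check, the joins between the ribosomal RNA loci in the lists were compared with the distance between the ribosomal RNA genes of the table, and 25 of 73 joins lay within 50 bp of it. Most joins lay further off, with a median absolute deviation of 1112 bp from that distance. The check therefore does not establish that the positions are the same. The table holds no exons, so the planned exon overlap was replaced by gene bodies of protein-coding genes, with introns and untranslated regions included. The ends of calls longer than 100 kb and of translocations, and the whole span of other calls, were used for overlap. An insertion has 1 breakpoint, because its second position is about its start plus the inserted length. The placements had first been run with both positions of insertions counted, which gave a gene share of 46.5% (placement permutation p = 0.0093), and this was changed after that result had been seen. The ranking of named calls, at first by reads summed over repeat calls, was likewise set back to the reads of a call, as planned.

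Genes to name were set before the data were examined. They were the genes of calls shared by all 5 filtered lists, of which there were none; in each library up to 6 private calls in protein-coding genes with the most reads, ties in order of position, with at most 3 genes each; the longest deletion, duplication and inversion and the translocation with most reads; and genes of the 3 fixed lists, 77 genes in all, met by a private call of at most 100 kb. All 77 identifiers matched the table. Calls shared by 2 or 3 libraries were named in addition, after the data were seen.

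Group differences were tested by exact two-sided permutation of libraries, type composition by 100000 reassignments of types to libraries, and gene and pericentromere shares by 10000 random placements with lengths kept, two-sided. Pericentromeric windows were 500 kb windows with a protein-coding gene density under 50% of the chromosome median. Chromosomes were taken to end at the last annotated gene. Lists were tested by Fisher's exact test, and Benjamini-Hochberg adjustment was applied over libraries, types or lists. Intervals are exact Clopper-Pearson at 95%. On simulated lists, 100% of 20 shared calls were recovered. Their copies were shifted by less than the matching window, so full recovery was fixed in advance and checks the code only. The placement test called 2% of 100 random sets of 60 calls at 0.05, and 86% of 50 sets enriched in genes. The simulated sets held no translocations, inverted duplications or calls grouped at a locus, and no set depleted in genes was simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were other lists, read minimums, matching rules, call types and lengths, window sizes and libraries left out. Those chosen only after seeing the data were repeat calls counted once or, in placements, all counted, inverted duplications left out, the caller's best positions, precise calls, unfiltered nuclear calls, libraries left out of shares, ends of longer calls in the gene lists, pairs with the pool added, and both positions of insertions. The other matching rules for named private calls and for like and unlike pairs, and the unfiltered lists for those pairs, were likewise not planned. The test of plant number in the pool had first compared calls of other types, and was replaced after its result had been seen because pooling can take a plant's calls under 5 reads.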

Results

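Structural variants were listed for 5 long-read whole-genome libraries of Arabidopsis thaliana, ecotype Col-0, each made from plants picked as mutants after their seeds had been irradiated. Seeds had been carried for 30 days at about 35 km altitude over Antarctica, or had received beams of hydrogen, helium, oxygen and titanium ions that simulate cosmic radiation. The beams gave 10.62, 3.165, 1.08 and 0.735 rad in that order. There were 2 Antarctic single-plant libraries (mutants 1 and 2), 2 simulated-radiation single-plant libraries (mutants 4 and 5), and 1 library that pooled 6 Antarctic plants. The Antarctic plants were labelled M0 and taken as frozen whole plants, and the simulated-radiation plants were labelled M1 and sampled as fresh single leaves, so exposure, generation and material cannot be separated here. No unirradiated library was analysed here. The files hold no sequencing depth. The evidence given for a call is its number of supporting reads, which ran from 5 to 27 in the filtered lists. The lists also label the positions of each filtered call as precise or imprecise.

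The first question was whether plants of the 2 exposures carried different numbers of structural variants. The authors' filtered lists held 43 and 21 calls in Antarctic mutants 1 and 2, and 55 and 44 calls in simulated-radiation mutants 4 and 5. Insertions were the only type whose counts did not overlap between the exposures, with 5 and 3 in the Antarctic plants and 14 and 8 in the simulated-radiation plants. Deletions numbered 9 and 1 in the Antarctic plants and 9 and 15 in the simulated-radiation plants. Translocations, joins between 2 chromosomes, were as many in both, with means of 13 and 12 calls. The mean over all types was 32.0 ± 15.6 calls (SD, n = 2) in Antarctic plants and 49.5 ± 7.78 (SD, n = 2) in simulated-radiation plants. The difference of 17.5 calls gave p = 0.333 in an exact two-sided permutation test, which is also the smallest p that 2 against 2 libraries can give. Counting repeat calls of the same event once lowered the difference to 10.5 calls (exact permutation p = 0.667), and the unfiltered lists gave 20.0 (exact permutation p = 0.667). The difference was 28.5 without mutant 1 and 6.5 without mutant 2, 3.5 for translocations and calls of at least 1 kb, 6.5 for calls with at least 8 reads and 2.0 with at least 10. No call within 1 chromosome had more than 10 reads in any list, so these read minimums favour translocations.

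**Figure D1:**
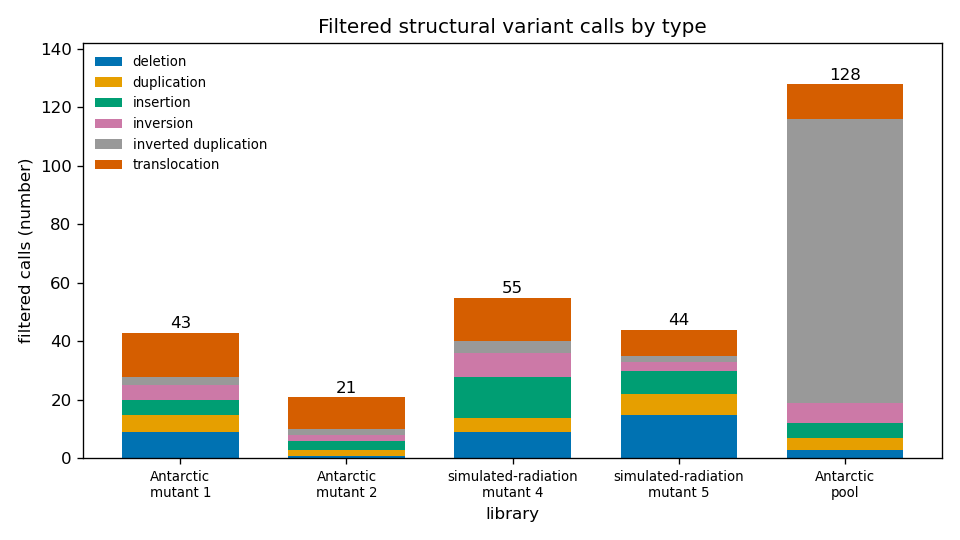
Filtered structural variant calls (number, y axis) in each of the 5 libraries (x axis), stacked by type, with the total above each bar. The pool of 6 Antarctic plants stands at 128 calls, 97 of them inverted duplications, against 21 to 55 calls in the single-plant libraries.

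The second question was which kinds of rearrangement the libraries held. In the Antarctic pool, short inverted duplications made up 97 of 128 calls, a share of 75.8% with an exact Clopper-Pearson 95% interval of 67.4% to 82.9%. Read counts of calls within 1 chromosome did not exceed 10, so read minimums favour translocations over this type. The share of inverted duplications was 60.0% among calls with at least 8 reads and 41.7% with at least 10. The same type made up 6.98% of calls in mutant 1, 9.52% in mutant 2, 7.27% in mutant 4 and 4.55% in mutant 5, or 11 calls in these 4 libraries together. The inverted duplications of the pool had a median predicted length of 42 bp, and 91 of the 97 were at most 100 bp long by this length. Both breakpoints lay within 100 bp of each other in 80 of them. They lay on all 5 chromosomes, for example at 27883061 on chromosome 1 in AT1G74150 with 10 reads, and at 12010412 on chromosome 4 in AT4G22900 with 9 reads. These examples were chosen after their values were seen. Translocations made up 34.9% of calls in mutant 1, 52.4% in mutant 2, 27.3% in mutant 4 and 20.5% in mutant 5. The type composition differed between the 5 libraries (permutation p = 1e-05, the smallest that 100000 reassignments can give) and no difference was found between the 4 single-plant libraries (permutation p = 0.274). Both tests compare libraries and not exposures, and the intervals cover counting error only.

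The 4 single-plant libraries held 113 calls on 1 chromosome, with a median length of 520 bp. The median was 108.5 bp in precise calls, 7388 bp in the unfiltered lists with their organelle calls, and again 520 bp in the nuclear calls of those lists. Of the 113 calls, 74 were shorter than 1 kb and 11 were longer than 100 kb. The longest call of all was an inversion in mutant 2 from 129495 to 26199077 on chromosome 5, with ends in AT5G01320 and AT5G65550 and 6 reads. The longest deletion ran from 2520493 to 25497729 on chromosome 1 in mutant 4, with 6 reads and its right end in ATTPS6 (AT1G68020), named for trehalose-6-phosphate synthase. Mutant 4 had other calls inside this span, such as an insertion at 14255823 on chromosome 1. Calls of this length are joins seen in split reads, and loss of the sequence between the ends was not tested. The longest deletions and inversions of mutants 1 and 5 and of the pool were labelled imprecise. So was the longest duplication of mutant 4. Genes at the ends of these calls are therefore less certain. In mutant 5 the longest deletion spanned 6774367 to 19031113 on chromosome 3 with 6 reads, and its ends lay in AT3G19520 and in PAD1 (AT3G51260), an alpha subunit of the 20S proteasome. The longest deletion of mutant 1 ran from 15686107 to 17527254 on chromosome 2 with 7 reads, one end in AT2G41990. In mutant 2 the only deletion was 107 bp long. The longest deletion of the pool joined 5544644 to 21761737 on chromosome 3 with 6 reads, its left end in ABCG29 (AT3G16340), a transporter gene of the ATP-binding cassette family. The longest inversions were 13552478 bp in mutant 1 (AT5G24890 and AT5G54460 at the ends), 12807269 bp in mutant 4 (one end in CRF10, AT1G68550, a cytokinin response factor), 8400 bp in mutant 5 and 17315712 bp in the pool (one end in AT3G51390). The longest duplications were 4091, 1377, 7388 and 635 bp in mutants 1, 2, 4 and 5, and 8443691 bp in the pool. The duplication of mutant 4 covered parts of the neighbouring genes AT5G46510 and AT5G46520.

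**Figure D2:**
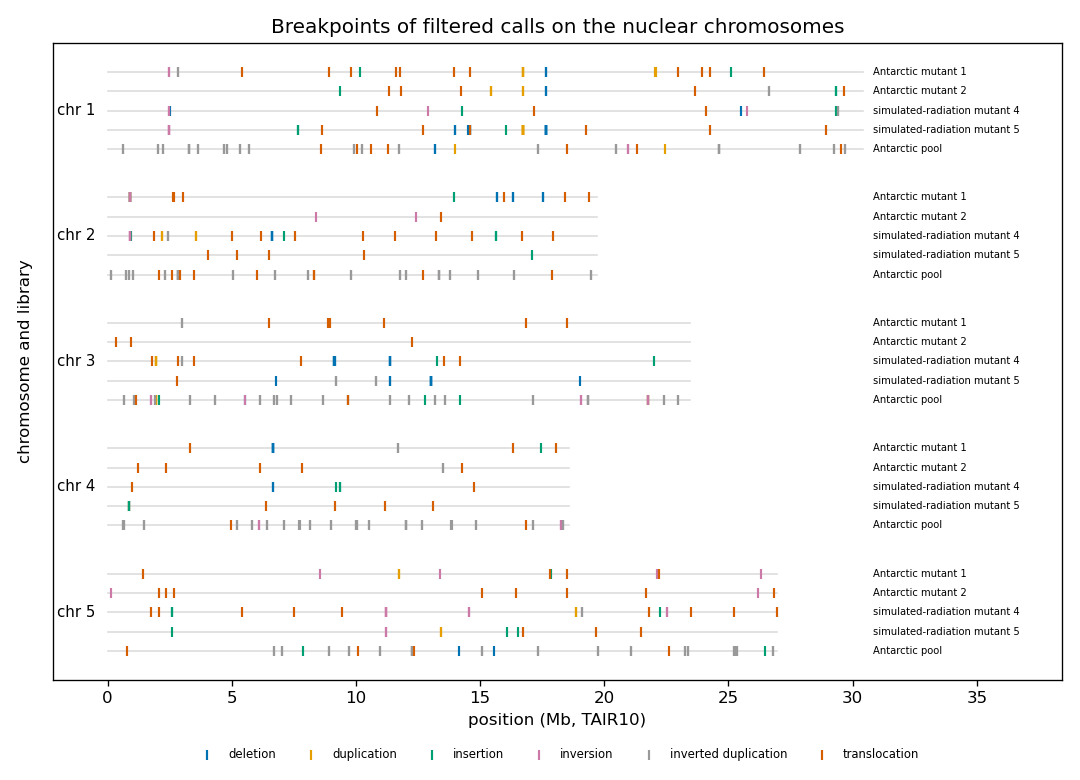
Positions (Mb, TAIR10, x axis) of the breakpoints of all filtered calls on the 5 nuclear chromosomes, a line for each library (y axis) and a colour for each call type. The inverted duplications of the Antarctic pool lie on all 5 chromosomes, with 16 to 20 distinct calls on each.

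The third question was which calls recur between plants, since a call found after separate exposures cannot be told from background of the seed stock or of the caller. No call was found in the filtered lists of all 5 libraries, or of 4. Of 243 distinct calls, 10 were found in more than 1 library, and 7 of these 10 were shared across both exposures. A duplication of 634 bp at 16737794 to 16738425 on chromosome 1 and a deletion of 108 bp at 17639366 to 17639475 on chromosome 1 were each found in mutants 1, 2 and 5, and neither overlapped a protein-coding gene. Mutants 4 and 5 shared an insertion of 1007 bp at 2610123 on chromosome 5 inside BIM1 (AT5G08130), which encodes a transcription factor of brassinosteroid signalling. An insertion of 91 bp at 29345234 on chromosome 1 in AT1G78040 was found in mutants 2 and 4. An inversion of 6347 bp at 2457157 to 2463191 on chromosome 1, in mutants 1 and 5, spanned AT1G07920, AT1G07930 and AT1G07940, a cluster of near-identical genes for translation elongation factor 1-alpha in which reads can map to more than 1 copy. Close calls of this inversion from 2456454 in mutant 4 and from 2457005 in mutant 5 had no partner within 500 bp at both ends in another library and were counted as private. The call of mutant 5 is also a repeat of the shared inversion in that library. A 94 bp deletion at 11354159 on chromosome 3 and an 8398 bp inversion at 11194464 on chromosome 5 were shared by mutants 4 and 5. Of the other 3 shared calls, a 47 bp deletion at 6666178 on chromosome 4 and a 1340 bp inversion at 891284 on chromosome 2 were in mutants 1 and 4, and a 2497 bp duplication at 1959228 on chromosome 3 was in mutant 4 and the pool. The printed ends of this inversion, 891284 and 891942, lay closer together than its predicted length. Mutants 1 and 4 had further calls around the inversion, between 890596 and 892629 on chromosome 2. These had no partner in another library and were counted as private. No translocation and no inverted duplication was shared.

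Of the filtered calls of the 4 single plants, 35 of 163 (21.5%) had a partner in another filtered list. Distinct calls were shared at a mean of 7.36% in the 2 pairs of like exposure and 6.10% in the 4 pairs of unlike exposure among the single plants, and no test was made because the 4 libraries form like pairs in only 3 ways. The pool shared 0.0% with mutants 1, 2 and 5 and 1.20% with mutant 4. With its pairs added, the means were 3.68% for like and 4.27% for unlike exposure, so the direction turned. The shared share was 50.9% in the unfiltered lists and 41.7% in their nuclear calls, and 9.80% and 7.14% with at least 8 and 10 reads. It was 13.5% without mutant 5 and 14.8% without mutant 4. Calls within 1 chromosome had at most 10 reads, so the read minimums favour translocations, and no filtered translocation was shared. The unfiltered lists of the 4 single plants also held 222 calls that touch an organelle and 60 joins between the ribosomal RNA loci. These are absent from the filtered lists, so the unfiltered shares cover other kinds of call.

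Calls with no partner in any other library's unfiltered list were taken as private. They numbered 35 and 17 in Antarctic mutants 1 and 2, 45 and 31 in simulated-radiation mutants 4 and 5, and 126 in the pool. The mean was 26.0 ± 12.7 (SD, n = 2) in Antarctic plants and 38.0 ± 9.90 (SD, n = 2) in simulated-radiation plants. This difference of 12 calls gave p = 0.667 in an exact two-sided permutation test, and was smaller than the spread of the Antarctic pair. Restricted to translocations and to calls of at least 1 kb, the difference was 0.0, and it was 3.5 with at least 8 reads and 0.5 with at least 10. Without mutant 5 it was 23.5, and without mutant 2 it was 3.5. The read minimums favour translocations here as well.

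Private calls in genes were ranked by their supporting reads in each library. Of those named below, the calls in GH9B14, AT5G41100, PIRL6, EXT13 and AT3G28790 were labelled imprecise, so their genes are less certain. The others were labelled precise. Read counts of calls within 1 chromosome did not exceed 10, so this ranking favours translocations. In mutant 4, a join between 10837819 on chromosome 1 and 11576470 on chromosome 2 had 21 reads, with its ends in AT1G30590 and in SERRATE (SE, AT2G27100), which acts in microRNA processing. The join with most reads in mutant 4, 27, linked 13552586 on chromosome 3 to 26968399 on chromosome 5 in AT5G67630. Further joins of mutant 4 ended in SPC98 (AT5G06680), a gamma-tubulin complex protein, with 18 reads, in LACS6 (AT3G05970), a long-chain acyl-CoA synthetase, with 14 reads, and in AT2G39990, an eIF3 subunit gene listed under the symbol EIF2, with 14 reads. A join with 11 reads had both ends in genes, VLN4 (AT4G30160), a villin, and AT5G53620.

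In Antarctic mutant 1, the translocation with most reads, 24, joined 3029589 on chromosome 2 in AT2G07290 to 18051035 on chromosome 4. Tic62 (AT3G18890), of the inner envelope import machinery, was at 6514695 on chromosome 3 in a join with 13 reads. PLSP1 (AT3G24590), a plastidic signal peptidase, was joined at 8971788 on chromosome 3 to AT1G65270 with 12 reads. ATS1 (AT1G32200), a plastid glycerol-3-phosphate acyltransferase, was joined to the transcription factor gene MYB2 (AT2G47190) with 10 reads. Ends also lay in AT5G04860 with 14 reads and AT1G25420 with 11 reads. In Antarctic mutant 2, the join with most reads, 19, linked 2368705 on chromosome 4 in AT4G04670 to 2077317 on chromosome 5. The others ended in AT5G07430 with 11 reads, GH9B14 (AT4G09740), a glycosyl hydrolase, with 9 reads, AT3G01980 with 8 reads and AT5G41100 with 7 reads. An inversion with 8 reads between 8372970 and 12429014 on chromosome 2 had an end in PIRL6 (AT2G19330).

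Simulated-radiation mutant 5 had no translocation with more than 9 reads, and its median of 7 reads was that of mutant 2. Its joins ended in CIP1 (AT5G41790), which encodes a COP1-interactive protein, and in AT1G65280 with 9 reads each, and in AT4G25780 with 8 reads. Its private calls within 1 chromosome included a 541 bp duplication at 13434416 on chromosome 5 in the extensin gene EXT13 (AT5G35190) with 7 reads. Another was an inverted duplication in AT3G28790 with 8 reads. Its predicted length was 62 bp, although its positions were 10811976 and 10814183 on chromosome 3. In the pool, translocations ended in the pyruvate dehydrogenase gene PDH-E1 BETA (AT1G30120), at 10585069 on chromosome 1, with 27 reads, in AT1G31550 with 26 reads, in AT5G03250 with 24 reads, in the subtilisin-like protease gene SLP3 (AT2G19170) with 20 reads, in AT2G19180 with 11 reads and in NAC042 (AT2G43000), a NAC transcription factor gene, with 10 reads. Over the 5 libraries, 47 of 62 private translocations had an end in a protein-coding gene, and 11 had both ends in one. Of the 124 ends of these translocations, 58 (46.8%) lay in such genes, against 53.8% ± 4.49 (SD over placements) in random placements. The difference was not detectable (placement permutation, adjusted p = 0.204, Benjamini-Hochberg over the types). These counts therefore show no excess of translocation ends in genes.

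**Figure D3:**
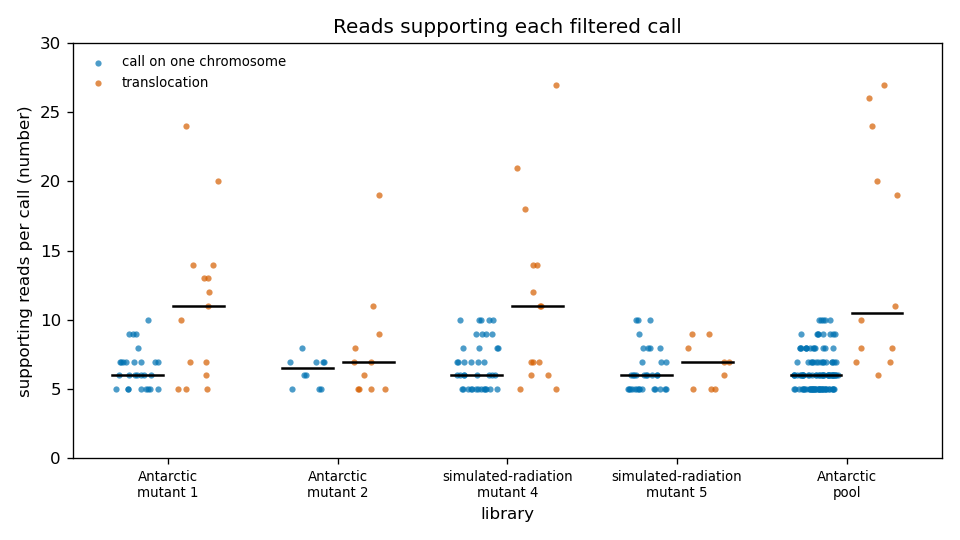
Supporting reads of each filtered call (number, y axis) in each library (x axis), with calls on 1 chromosome and translocations apart; each point is a call and each bar a median. Calls on 1 chromosome have 5 to 8 reads in Antarctic mutant 2 and 5 to 10 in the other libraries, and translocations reach 27 reads.

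Breakpoints were set against 10000 random placements of the same calls on their chromosomes. Fewer breakpoints than placed lay in protein-coding genes, 216 of 458 (47.2%) against a mean of 54.0% ± 2.84 (SD over placements) with p = 0.0147 in this placement permutation test. Antarctic mutant 1 stood at 34.8% (placement permutation, adjusted p = 0.0145, Benjamini-Hochberg over the 5 libraries) and simulated-radiation mutant 4 at 36.1% (adjusted p = 0.0145). By the same permutation, the values were 44.7% in mutant 2 (adjusted p = 0.392), 47.3% in mutant 5 (adjusted p = 0.441) and 51.9% in the pool (adjusted p = 0.652). Each distinct call was placed on its own, although some calls lay at the same locus. Mutants 1 and 4 both had several calls outside protein-coding genes between 890596 and 892629 on chromosome 2. The p values do not allow for such grouping. By type, deletions had 28.9% of breakpoints in genes (permutation, adjusted p = 0.069 over the 6 types) and inverted duplications 53.9% (adjusted p = 1). The merged result did not pass 0.05 without mutant 1 (48.4%, permutation p = 0.0695), without mutant 4 (48.6%, p = 0.0815), with at least 8 reads (47.4%, p = 0.162) or with precise calls alone (47.3%, p = 0.128). It did pass with at least 10 reads (36.5%, permutation p = 0.0081), with deletions, duplications and inversions only (36.0%, p = 0.002) and without inverted duplications (41.7%, p = 3e-04).

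Of the same breakpoints, 16.6% lay in the gene-poor windows called pericentromeric here, against 15.5% ± 2.12 in the placements (permutation p = 0.603). These windows were set by gene density alone and not by centromere position. Among the types, duplications were the one past the threshold, with 13 of 26 breakpoints (50.0%) in these windows against a placed mean of 15.8% (permutation, adjusted p = 0.0144 over the 6 types). Mutant 5 stood at 32.7% against 15.0% (permutation, adjusted p = 0.025), and the other libraries lay between 14.0% and 18.1%. Each distinct call was again placed on its own, so nearby calls of a library counted as independent. Without inverted duplications the merged share was 20.6% (permutation p = 0.0339).

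The fixed gene lists asked whether private calls of at most 100 kb met genes of DNA damage response and repair, of chlorophyll and plastid biogenesis, or of shoot, root and leaf development. None of the 31 repair genes, 20 plastid genes and 26 development genes was overlapped, against 84 of the other protein-coding genes, a share of 0.305% (Fisher's exact test, two-sided, p = 1 for each list and adjusted p = 1). At this share, lists of this size would rarely be met at all, so the test could not show that a list was spared. With the ends of translocations and of longer calls added, SERRATE of the development list was the only list gene met (Fisher's exact p = 0.141, adjusted p = 0.422).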

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

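All tests of explanations in this part were chosen only after the results were seen. Calls that touch an organelle were outside the comparisons, since the filtered lists hold none. The unfiltered lists held 52 and 56 of them in Antarctic mutants 1 and 2, 70 and 44 in simulated-radiation mutants 4 and 5, and 39 in the pool. Joins between the ribosomal RNA loci of chromosomes 2 and 3 numbered 15 and 16 in mutants 1 and 2, 13 and 16 in mutants 4 and 5, and 13 in the pool, and they were likewise outside the comparisons.

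Inverted duplications were the one type in excess in the Antarctic pool. More plants in the pool could give at most 24 such calls if each of its 6 plants held as many as the highest single-plant library, 4, but the pool had 97, which argues against it only as far as the pooled plants resemble the single ones. Greater read depth of the pool was set against the reads behind the ribosomal joins, which numbered 245 in the pool and 370 in the highest single-plant library. These reads were thus not more numerous in the pool. Whether they follow depth is not known from the lists, so depth is left open. Reads that fold back on themselves may give such short calls, and the calls fell on the 5 chromosomes without a detectable departure from chromosome length (permutation p = 0.281), a weak test that leaves this open, as it would any process spread over the genome. Differences of the pool plants in age, 17 and 21 days against 44 and 45 days, were not tested.

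Translocation calls were found in all 5 libraries, 9 to 15 in each. A balanced exchange between chromosomes would leave a second join of opposite strands nearby, but 0 of 62 calls had one within 50 kb in the same library. A second join with fewer than 5 reads would not be listed and depth is unknown, so this absence does not exclude an exchange. A pair of joins of opposite strands was split between mutants 1 and 2, with ends 1839 and 1841 bp apart and 6 and 5 reads. As these are separate plants, the pair does not show both joins of an exchange in either plant. These 2 calls cannot be told from background of the seed stock or of the caller. For mapping between repeats around centromeres, the pericentromeric share was 15.3%, beside 15.5% ± 3.23 (SD over placements) in random placements. The calls together thus showed no excess in these windows. The windows were set by gene density alone, so such mapping is not excluded for part of the calls. Dispersed repeats, and joins of separate molecules during library making, were not tested and could remain.

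More calls in simulated-radiation than Antarctic plants is a difference that the exact test cannot separate from chance. Repeat calls of the same event explain part of it at most, since 10.5 of the 17.5 calls of difference were left with distinct calls. Greater read depth of the simulated-radiation libraries cannot be told apart, because the reads behind the ribosomal joins were 370 and 318 in the Antarctic and 291 and 364 in the simulated-radiation plants, a mean difference of -16.5. Exposure, generation and material stay open and were not tested apart.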

How the results depend on the processing

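Of 115 alternative values, 96 kept their direction and side of 0.05, or lay within the spread. The difference in calls was positive under all 14 alternatives, from 2.0 to 28.5, in a design that cannot pass 0.05. The difference in private calls was 0.0 with calls of at least 1 kb or translocations, 3.5 with at least 8 reads and 0.5 with at least 10, and ran from 3.5 to 23.5 with single libraries left out. The shared share was 50.9% in unfiltered lists, 41.7% in unfiltered nuclear calls, 9.80% with at least 8 reads and 7.14% with at least 10, and 13.5% to 21.1% with libraries left out. The unfiltered shares include joins between the ribosomal RNA loci, which the filtered lists lack. The gene share lost its call with at least 8 reads (47.4%) and with precise calls (47.3%), kept it with at least 10 reads (36.5%), with deletions, duplications and inversions only (36.0%) and without inverted duplications (41.7%), and ran from 41.8% to 48.6% with libraries left out. The pericentromeric share passed 0.05 without inverted duplications (20.6%). With libraries left out it ran from 15.0% to 19.1%, and it turned below the placements, at 15.0%, without mutant 5. The inverted duplication share of the pool ran from 41.7%, with at least 10 reads, to 76.7%, and in 5 of the 11 alternatives it could not change, since these left the calls of the pool as they were. The p of these rows tests the type composition over the libraries and not this share. Median length was 7388 bp in unfiltered lists, 520 bp in their nuclear calls and 108.5 bp in precise calls. Gene list hits were 1 with the ends of longer calls added. Sharing of like minus unlike pairs was 1.25 percentage points, 4.75 in unfiltered lists, and turned to -0.591 with the pairs of the pool added. The cause of these changes was not tested. The precise, unfiltered nuclear, inverted duplication, pool pair, longer-end and most left-out-library alternatives were chosen after seeing the data. The 4.75 for pairs in unfiltered lists and the 76.7% share, from repeat calls counted once, were likewise not planned. Nuclear chromosomes alone changed nothing because the filtered lists hold no organelle calls, and without the pool no type share of the pool exists. Depth is unknown, so calls under 5 reads cannot be counted. Calls within 1 chromosome had at most 10 reads, so all values with a raised read minimum favour translocations.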

Other observations

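The values in this part were looked at only after the data had been seen, and none was tested. In the unfiltered lists, joins of a nuclear chromosome to an organelle numbered 146, and 100 of them led to the mitochondrion. Of these 100, 96 lay between 3244110 and 3509084 on chromosome 2, near where the Col-0 reference carries a large mitochondrial insertion. Of 102 distinct joins to an organelle, 3 were found in all 5 libraries and 81 in 1 library each. Of these 81, 50 led to the mitochondrion and 31 to the chloroplast. Since nearly all mitochondrial joins lay in the chromosome 2 interval, one found in 1 library is not shown to be a transfer particular to that library. Joins to the chloroplast numbered 46, of which 32 lay on other chromosomes than 2. A join between 7104291 on chromosome 3 and the chloroplast was found in mutants 1, 4 and 5 with 62 reads in all.

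The read counts of calls within 1 chromosome did not exceed 10 in any of the 10 lists, filtered and unfiltered, while 24 of 62 filtered translocations had more than 10. The repeat calls of the same event added up to more. The 108 bp deletion at 17639366 on chromosome 1 had 30 reads over its repeat calls in mutant 5, and the 634 bp duplication at 16737794 had 26. Whether the reads of repeat calls are different reads is not known from the lists.

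Mutants 1 and 2 each had a translocation between chromosomes 1 and 5 whose ends lay close together but beyond the matching window. Mutant 1 joined 11792240 to 18492447 with 6 reads, and mutant 2 joined 11794079 to 18490606 with 5 reads. The ends lay 1839 and 1841 bp apart, with opposite strands. Both joins had been counted as private.

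In the pool, a deletion and an inversion joined 5544644 and 5544888 on chromosome 3, inside ABCG29, to 21761737 and 21767065, and a duplication and an inversion of 5320 and 5322 bp lay between these far ends over AT3G58860. These 4 calls had 6 reads each. In mutant 5, AT4G01985 on chromosome 4 held 3 private calls, a 46 bp deletion, a 202 bp duplication and a 183 bp insertion. Mutant 5 also had deletions of 27000 bp from 14511722 and of about 36017 bp from 14545704 on chromosome 1, in a region without protein-coding genes at either call.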
